A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

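Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA, in budding yeast grown at 30 °C to mid-logarithmic phase. The labels gave 2 wild-type (WT) libraries and 2 libraries from cells lacking SWC4 (swc4Δ), with genotype and replicate number taken from each library's own label. Nothing in the labels said that replicates came from separate cultures, so the spread between libraries of a genotype may be technical. Only the exact permutation tests of 2 against 2 libraries use that spread. The other tests compare regions, promoters or peaks and do not measure it.

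Each library had 1 deposited peak list. Per the submitters' processing notes, reads were handled with Trim Galore 0.5.0, Bowtie2 2.3.1, Picard 2.18.7, SAMtools 1.4 and deepTools 1.5.11 on the sacCer3 build, with no role or order stated. The peak caller, its settings and any shift of reads for the Tn5 cut were not given in the sources used here. Peak names in the deposited lists carried the library's name, so peaks were called per library. In the deposited lists each peak had a fold enrichment (a ratio over background), a −log10 p-value and a −log10 q-value, and a summit position. The deposited folds of every library lay on 1 evenly spaced ladder, with 100% of peaks within 0.01 of a whole step, and each fold had 1 p-value. A Poisson test with 1 background per library gave back the deposited −log10 p-values with a largest error of 0.000157. The authors' lists therefore used a single background for the whole genome, with no correction for a chromosome's copy number. The same ladder gave the depth: the background pileup was 22.6 and 24.0 fragments in the WT libraries and 24.4 and 25.5 in the swc4Δ libraries. The whole series had 2 further lists, 1 per genotype, each with a deposited whole-number score per region. Their caller and whether they pooled replicates were not given in the sources used here, and their genotype came from the code their names shared with the per-library lists. They are called the authors' genotype lists. Folds and scores are the authors' own and were used only to describe and rank peaks within a list.

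Peaks of the 4 libraries were merged into regions where they shared at least 1 bp. A region was gained when it held a peak in both swc4Δ libraries and in neither WT library, lost in the opposite case, and reproducible when it held a peak in both libraries of at least 1 genotype. Genes came from the RefSeq table of assembly R64, the assembly that sacCer3 names, with 6431 nuclear genes. Strand was read from the systematic name, which lacked it for 1 gene. Feature classes were tRNA, snoRNA, snRNA and rRNA genes, the rDNA array, the outer 20 kb of each chromosome, promoters (500 bp upstream of each of 6002 protein-coding genes) and gene bodies only. Chromosome ends were set at the largest coordinate in the gene table or the lists. Annotated telomeres, centromeres, replication origins and retrotransposons were not analysed here. The rDNA is present in many copies that the build holds only in part, and tRNA genes of 1 family share sequence, so peaks there depend on how reads with several matches were handled, which was not given in the sources used here.

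Feature classes among gained or lost regions were compared with the other reproducible regions by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 7 classes in each direction. The share of features with a peak was compared between genotypes by an exact permutation test of 2 against 2 libraries, whose smallest two-sided p is 0.333, so no such comparison could pass 0.05. Within a library, peaks at a class were compared with 1000 circular shifts of the peaks along each chromosome, adjusted over 36 tests. Ranks of peaks within a list were tested with 100000 resamples, adjusted over 16 tests. Promoters of 14 gene lists were compared with the other reproducible promoters by Fisher's exact test, adjusted over the lists. Regions and promoters are not replicate cultures, so these p-values describe these 4 libraries.

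Apart from those named below as later, tests, alternatives, gene lists and the rule for named regions were chosen before the data were examined. By that rule SWC4 came first, followed by the 12 gained and 12 lost regions with the highest mean rank of fold over the libraries that held them, up to 10 features per class and direction, and up to 6 promoters per gene list and direction. Alternatives were a stricter threshold (−log10 q of at least 5), equal numbers of peaks per list, each library left out and a 50% overlap. Others were summits with 100 bp on each side, features extended by 200 bp, chromosome ends of 10 kb and promoters of 300 bp. The last was a replicate block, whose class tests used other calls. There a gain was a peak in a swc4Δ library and none in the same-numbered WT library, and a loss the reverse. Both replicate numbers were pooled, and 1 region could enter under each, so the pooled counts were not independent. Repeats without chromosomes IV, V, VIII and XI, and without these and XII, the terminal 1 kb of chromosomes as a class, the comparison of chromosomes, the merged region around each gained or lost feature, and gene lists and promoter counts with equal numbers of peaks or a library left out were chosen after seeing the data. Merging, calls and class tests were run on simulated lists. Of 200 planted gains 200 were recovered, 80 of 80 planted losses were called, and 0 of 40 shift tests on random positions had p under 0.05. The simulated libraries all held the peaks of WT replicate 1, slightly shifted, with none missing from a library. In the real lists 1057 of 3469 merged regions lay in 1 library only. Recovery was thus nearly fixed by the setting, so it checks the code and gives no error rate for the real calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.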

Results

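ATAC-seq was carried out on budding yeast of the laboratory strain BY4741, named in the labels of both genotypes, with 2 WT and 2 swc4Δ libraries. Swc4 is a subunit shared by the SWR1 chromatin remodeller, which places the histone variant Htz1, and the NuA4 histone acetyltransferase. The series title names telomeres, tRNA genes and the rDNA as the places of interest, and these were the primary classes here. The peak lists held 2354 and 2115 peaks in the WT libraries and 2826 and 2368 in the swc4Δ libraries, at background pileups of 22.6, 24.0, 24.4 and 25.5 fragments in the same order. SWC4 itself (YGR002C, chromosome VII, 498476 to 499906, sacCer3) had no peak over the gene or its promoter in any of the 4 libraries or in either of the authors' genotype lists, so the deletion could not be checked from peaks.

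The first comparison asked how far the map of open chromatin differed between the genotypes. Most reproducible open regions were shared: of 2181 regions found in both libraries of a genotype, 1328 held a peak in all 4 libraries. Gained regions numbered 305, or 16.1% of the 1896 regions found in both swc4Δ libraries, and lost regions numbered 92, or 5.70% of the 1613 found in both WT libraries. The strongest gains lay upstream of JEN1, a lactate and pyruvate transporter, at the right end of chromosome VI by YFR057W, and in the promoter of BAR1, a protease that degrades α-factor. The strongest losses lay in the promoter shared by MDG1 and APC1 and in those of MF(ALPHA)1, an α-factor gene, and SAG1, the α-agglutinin.

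The JEN1 region (chromosome XI, 20222 to 21216) had a fold over background of 4.73 and 3.66 in the swc4Δ libraries, and the BAR1 region (IX, 321895 to 322276) 4.10 and 3.32. Other leading gains lay in the promoters of AQY2, an aquaporin gene, HXT13 and the pair IMA5 and HXT8, which code for an isomaltase and hexose transporters, YEF3, a translation elongation factor gene, PRM5 and NUP100. The gap between RQC1 and SWR1, the gene of the remodeller's ATPase, was gained as well (IV, 1135408 to 1135744; folds 3.98 and 2.91). Among losses, the MDG1 and APC1 region (XIV, 310147 to 310527) had folds of 3.09 and 2.48 in the WT libraries, and MF(ALPHA)1 (XVI, 193023 to 193678) 2.63 and 2.56. PEP8, MKS1, LIA1, SEC4, YMR196W, SOV1 and the pair YOR365C and SCP1 lost promoter peaks, while the lost peaks at MDH2 and BBC1 lay inside the gene.

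Peaks per library averaged 2234.5 ± 169 (SD, n = 2) in WT and 2597 ± 324 (SD, n = 2) in swc4Δ, with an exact permutation p of 0.333 (two-sided), the smallest that 2 against 2 libraries allow. Peaks covered 1208 ± 120 kb (SD, n = 2) in WT and 1521 ± 206 kb (SD, n = 2) in swc4Δ (exact permutation p = 0.333). The Jaccard index of covered bases was 0.587 and 0.599 for the pairs of 1 genotype and averaged 0.494 for the 4 pairs across genotypes. Leaving out swc4Δ replicate 2 raised the gained regions to 759, leaving out swc4Δ replicate 1 gave 527 and leaving out WT replicate 1 gave 514, so the count of 305 depends on requiring both libraries. Lost regions went to 288, 277 and 263 without WT replicate 1, WT replicate 2 and swc4Δ replicate 1, and to 20 at the stricter threshold.

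The gains were unevenly spread over the chromosomes. Chromosome XI held 113 of the 305 gained regions, and 51.1% of its 221 reproducible regions were gained (odds ratio 9.63, adjusted p = 1.38e-44, Fisher's exact test, 16 chromosomes tested). That odds ratio was 5.997 without swc4Δ replicate 1 and 5.52 at the stricter threshold. Chromosome IV held 72 (odds ratio 1.92, adjusted p = 1.71e-04) and chromosome VIII 28 (odds ratio 2.13, adjusted p = 0.00373) by the same exact test. Chromosome V, with 11 of its 127 reproducible regions gained (odds ratio 0.568, adjusted p = 0.105, same exact test), was not rich in gains and was set apart with these 3, after seeing the data, because swc4Δ replicate 2 had 175 peaks there, against 136 and 130 in WT and 137 in swc4Δ replicate 1. Chromosome XII, with a similar excess in the other swc4Δ library (259 peaks in replicate 1, against 203 and 191 in WT and 189 in swc4Δ replicate 2), was nevertheless kept. Together IV, V, VIII and XI held 73.4% of the gains and 4 of the 92 losses on 27.7% of the genome's length. Since these chromosomes were set apart for their gains or swc4Δ peaks, a balance on the rest is partly selected. It was also not examined at the stricter threshold, which left 229 gains and 20 losses over all chromosomes. At the main threshold gains and losses were 65 and 85 without XII as well, and nearly equal, at 81 and 88, on the other 12 chromosomes. Losses were uneven among these: they were over-represented on XIV (14 lost and 5 gained; odds ratio 3.14, adjusted p = 0.00342), XVI (14 and 5; odds ratio 2.97, adjusted p = 0.00411) and III (6 and 1; odds ratio 3.67, adjusted p = 0.0330) by the same exact test, while XII and XV had 16 gains each and 3 and 4 losses.

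**Figure D1:**
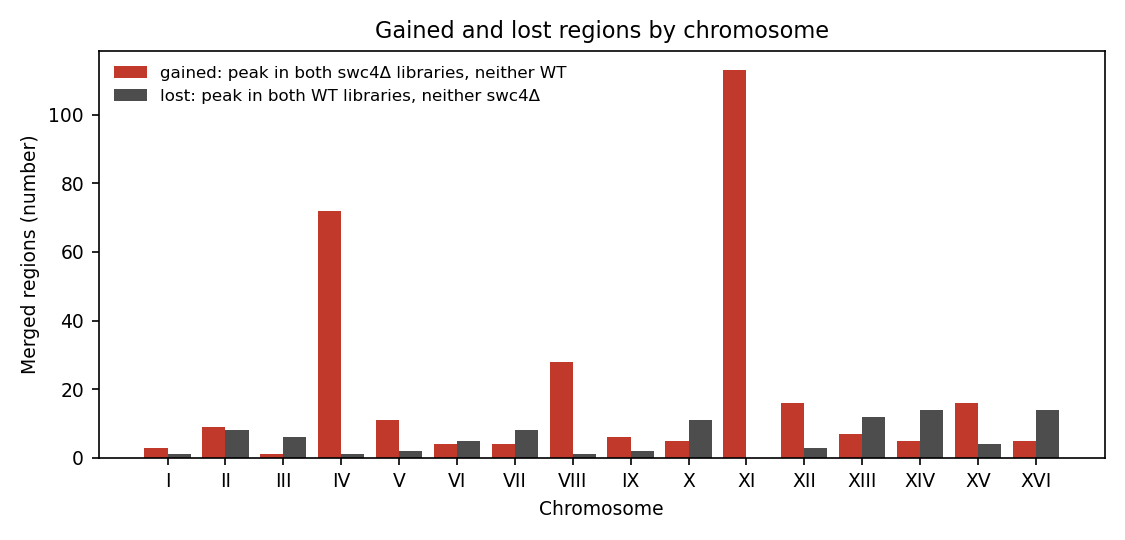
Number of merged regions gained (red bars) and lost (grey bars) in swc4Δ on each of the 16 chromosomes. Chromosome XI has the tallest bar, with 113 gained regions and 0 lost.

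On chromosome XI the lists held 125 and 107 peaks in WT and 345 and 288 in swc4Δ, covering 11.01%, 9.25%, 41.5% and 30.4% of its length. Its gains fell in 10 of 10 equal segments of the chromosome, with 7 to 15 in each. Regions of XI found in all 4 libraries had a median fold, relative to that on the other chromosomes of the same library, of 0.986 and 0.940 in WT and 1.28 and 1.18 in swc4Δ. The same measure for IV was 0.972 and 0.993 in WT and 1.05 and 1.14 in swc4Δ, for V 1.02 and 1.08 in WT and 0.979 and 1.14 in swc4Δ, and for VIII 0.972 and 0.955 in WT and 0.974 and 1.04 in swc4Δ. On V and VIII swc4Δ replicate 1 was thus level with or below a WT library. Both swc4Δ libraries lay below both WT libraries on III (1.03 and 1.04 in WT, 0.896 and 0.859 in swc4Δ), VI (0.915 and 0.933, 0.854 and 0.833), XIV (1 and 1, 0.897 and 0.897), VII, IX and XV. On the other 12 chromosomes the lists held 1698 and 1542 peaks in WT and 1814 and 1281 in swc4Δ, so that swc4Δ replicate 2 had fewer than either WT library.

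**Figure D2:**
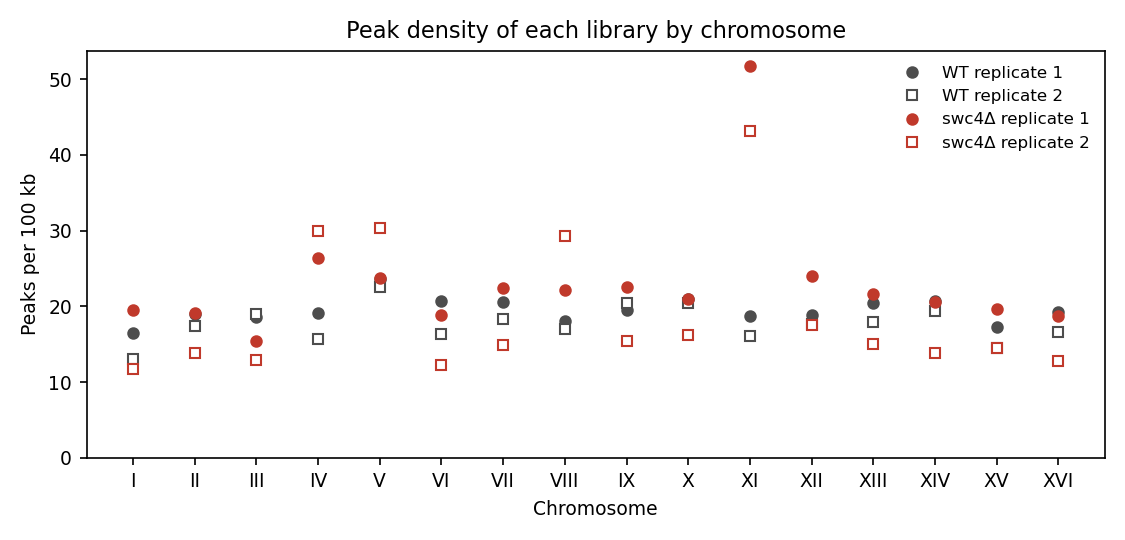
Peaks per 100 kb of each chromosome for each of the 4 libraries (grey, WT; red, swc4Δ; filled circles, replicate 1; open squares, replicate 2). On XI the swc4Δ libraries reach 51.7 and 43.2 peaks per 100 kb against 18.7 and 16.05 in WT.

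The second comparison concerned tRNA genes. Of the 275 nuclear tRNA genes, 182 and 134 overlapped a peak in the WT libraries and 241 and 191 in the swc4Δ libraries. The share was 57.5% ± 12.3 (SD, n = 2) in WT and 78.5% ± 12.9 (SD, n = 2) in swc4Δ, a difference of 21.1 points. The difference was 12 points without swc4Δ replicate 1 and 12.4 without WT replicate 2. A peak in both swc4Δ libraries and neither WT library was seen at 25 tRNA genes, and the opposite at 0, while 113 tRNA genes had a peak in all 4 libraries and 26 in none. For 16 of the 25 the merged region held no WT peak, among them YNCK0010W (XI, 302918 to 303023; folds 3.70 and 2.76), TRT2 on XI, YNCD0014C on IV (folds 3.63 and 2.68), YNCL0007W on XII and YNCI0005W on IX. The peak over TRT2 (folds 3.78 and 2.57) also covered the promoter of STE6, so it was counted for both. For the other 9 a WT peak lay in the same merged region and stopped short of the gene, as at YNCJ0014C (X, 374506 to 374577), where folds were 2.03 and 2.20 in WT and 3.59 and 2.91 in swc4Δ. The same held for YNCK0019W, with 3.90 and 4.32 in WT and 7.84 and 5.59 in swc4Δ, and for YNCK0006C, YNCK0008W and SUP6.

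Although both swc4Δ libraries lay above both WT libraries, the exact permutation test gave p = 0.333, the smallest it allows. Of the 25 tRNA genes, 14 lay on IV, V, VIII and XI, where peaks of all kinds were more frequent in swc4Δ. On the other 12 chromosomes the shares of 200 tRNA genes were 67.5% and 52.5% in WT and 87.0% and 61.0% in swc4Δ, so the genotypes overlapped there, with 11 tRNA genes gained, 8 of them in regions without a WT peak, and 0 lost. In every library tRNA genes held 4.47 to 5.55 times as many peaks as shifted peaks gave (adjusted permutation p = 0.00225 in each library). Among regions, tRNA genes made up 17 of the 305 gained and 180 of the 1876 other reproducible regions (odds ratio 0.556, adjusted p = 0.0543, Fisher's exact test). This odds ratio depended on the setting: it was 1.03 at the stricter threshold, 1.05 without IV, V, VIII and XI and 1.21 without WT replicate 1, and it passed the threshold without swc4Δ replicate 1 (0.378) or replicate 2 (0.645). No lost region out of 92 touched a tRNA gene, against 197 of the 2089 others (odds ratio 0, adjusted p = 5.99e-04, Fisher's exact test), a call not reached with the 20 lost regions of the stricter threshold, and without swc4Δ replicate 1 the odds ratio was 0.457. Over all peaks the median fold percentile of those at tRNA genes was 54.3 and 56.1 in WT and 54.9 and 57.3 in swc4Δ, apart from other peaks only in swc4Δ replicate 2 (adjusted permutation p = 0.00430). In the shared regions tRNA genes ranked near the middle, with median fold percentiles of 46.5 and 43.9 in WT and 44.7 and 44.1 in swc4Δ. The authors' genotype lists covered 59 tRNA genes in WT and 233 in swc4Δ, without replicates. These lists differed in length, with 1002 regions in WT and 2602 in swc4Δ, of which 5.69% and 8.76% touched a tRNA gene. The WT list also fell below the 182 and 134 tRNA genes with a peak in the WT libraries.

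The third comparison concerned chromosome ends. Peaks in the outer 20 kb numbered 57 and 55 in WT and 95 and 68 in swc4Δ, and of the 32 terminal 1 kb segments 14 and 14 held a peak in WT and 17 and 17 in swc4Δ. The segments with a peak in both swc4Δ libraries and in neither WT library were the right end of VI (folds 4.26 and 3.28) and the left end of VIII (folds 2.72 and 2.11). Every segment with a peak in a WT library also had 1 in both swc4Δ libraries. Regions in the outer 20 kb made up 13 of the 305 gained and 1 of the 92 lost.

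The number of peaks in the outer 20 kb, 56 ± 1.41 (SD, n = 2) in WT and 81.5 ± 19.1 (SD, n = 2) in swc4Δ, gave an exact permutation p of 0.333. On the other 12 chromosomes these numbers were 41 and 40 in WT and 54 and 39 in swc4Δ, so the genotypes were not separated there. Chromosome ends were not enriched among gained regions (odds ratio 1.53, adjusted p = 0.357, Fisher's exact test), and with ends of 10 kb the odds ratio was 0.742. Without swc4Δ replicate 2 it was 1.91 and passed the threshold (adjusted p = 0.00738, Fisher's exact test). All 4 libraries had fewer peaks in the outer 20 kb than shifted peaks gave, at 0.449 and 0.481 times in WT and 0.637 and 0.548 times in swc4Δ (adjusted permutation p = 0.00899 in each). The terminal 1 kb went the other way, at 1.74 and 1.96 times in WT and 1.78 and 2.29 times in swc4Δ. Adjusted permutation p there was 0.0557, 0.0322, 0.0180 and 0.00423 in the same order. Gene families near the ends share sequence, so peaks there may also depend on how reads with several matches were handled, which was not given. The authors' genotype lists touched 16 terminal segments in WT and 21 in swc4Δ.

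The fourth comparison concerned the rDNA array on chromosome XII (451575 to 489469). The same pair of places was open in all 4 libraries, and no rDNA region was gained or lost. The first, by RDN5-1 and RDN37-2, spanned 459551 to 460854 in WT replicate 1 and was the strongest peak of every list, with folds of 12.7 and 12.1 in WT and 12.7 and 11.3 in swc4Δ. The second, at the 5S rRNA gene RDN5-6, had folds of 5.55 and 4.96 in WT and 7.09 and 5.40 in swc4Δ. The authors' genotype lists held 3 regions in WT and 4 in swc4Δ, the additional 1 lying at RDN37-1 (451361 to 451820). Because the build carries only part of the array, these peaks may sum over copies and cannot show how many copies are open.

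The fifth comparison covered promoters, gene bodies and small RNA genes. Fewer gained and lost regions than other regions touched a promoter: 218 of the 305 gained regions (71.5%) and 49 of the 92 lost ones (53.3%), against 88.1% and 87.2% of the other reproducible regions. Gained and lost regions were also narrower, with median widths of 456 and 410 bp against 811.5 bp for regions in all 4 libraries. Merging alone would give such a gap, since gained and lost regions join peaks of 2 libraries and the others peaks of 4. Gene bodies only made up 56 of the gained and 41 of the lost regions. Of 6002 promoters, 42.5% ± 5.48 (SD, n = 2) had a peak in WT and 50.3% ± 7.999 (SD, n = 2) in swc4Δ, with 314 gained and 63 lost. Of these, 40 gained and 11 lost promoters lay in a merged region that held a peak of the other genotype outside the promoter. On the other 12 chromosomes 85 promoters were gained and 63 lost, so the excess of gains came mostly from IV, V, VIII and XI. Without those chromosomes the difference in the share of promoters with a peak was 1.53 points, against 7.83 over all. Gained promoters were 591 without WT replicate 1 and 718 without swc4Δ replicate 2, and lost ones 107, 205 and 271 without WT replicate 1, WT replicate 2 and swc4Δ replicate 1. LSR1, the U2 snRNA gene on chromosome II, was overlapped by a peak in the swc4Δ libraries only, but the merged region beside it (679835 to 680717) held peaks in all 4 libraries, with folds of 3.30 and 3.16 in WT and 3.70 and 3.06 in swc4Δ.

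The odds ratio of promoters was 0.340 among gained regions (adjusted p = 1.11e-11) and 0.168 among lost regions (adjusted p = 5.63e-14), and that of gene bodies only was 3.18 (adjusted p = 2.39e-09) and 11.3 (adjusted p = 2.28e-21), all by Fisher's exact test. With summits of equal width the promoter odds ratio among gains was 0.555. Promoter peaks ranked high in every list, with median fold percentiles of 55.4 to 59.2 (adjusted permutation p = 8.00e-05 in each library). Of 2817 reproducible promoters 1867 had a peak in all 4 libraries. A region with a peak in both genotypes can be neither gained nor lost, so the odds ratios of both classes may partly follow from how the calls were defined. Gene bodies were no longer over-represented among gains without IV, V, VIII and XI (odds ratio 1.41, adjusted exact p = 0.659, and 0.851 without XII as well) or with equal numbers of peaks (odds ratio 1.97, adjusted exact p = 0.106), and among the 20 losses of the stricter threshold neither class passed, with gene bodies only at an odds ratio of 7.91 (adjusted exact p = 0.0717). Among losses, leaving out 1 library moved the odds ratio of gene bodies to between 2.39 (without swc4Δ replicate 1) and 27.1 (without WT replicate 1) and that of promoters to between 0.0657 and 0.580 (the same libraries, in the opposite order). Without WT replicate 1 the promoter odds ratio among gains was 0.891 and that of gene bodies 0.783, with neither past the threshold. The share of promoters with a peak overlapped between genotypes (exact permutation p = 0.667). Of 76 snoRNA genes, 31.6% ± 9.30 (SD, n = 2) had a peak in WT and 34.9% ± 8.37 (SD, n = 2) in swc4Δ, with 3 gained and 2 lost (exact permutation p = 0.667). snoRNA genes were in 3 gained and 2 lost regions, and snRNA genes in 1 gained and 0 lost, with no class past the threshold.

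**Figure D3:**
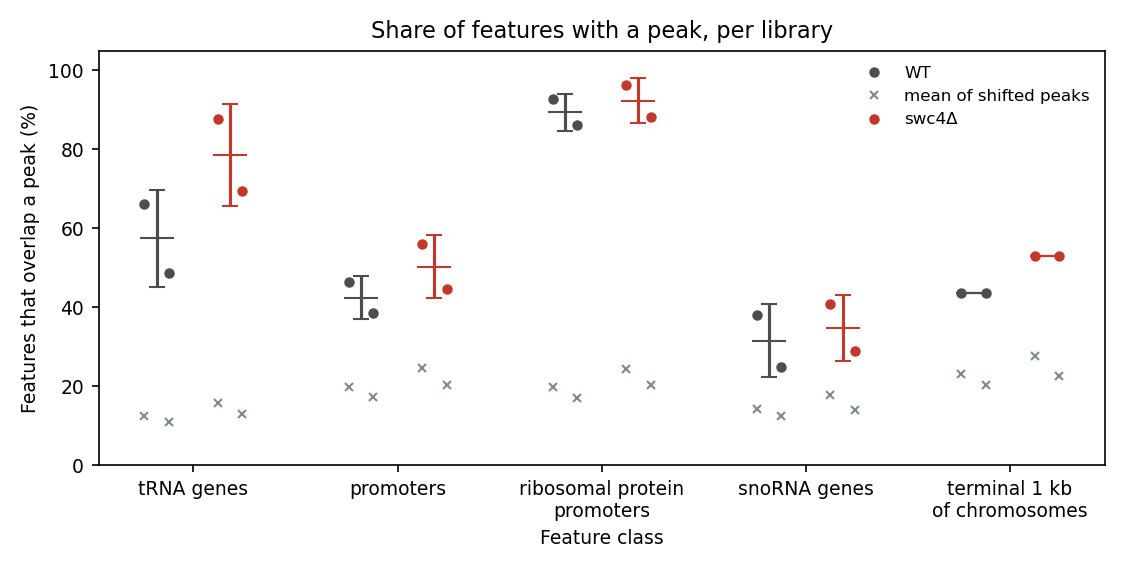
Share of features of each class that overlap a peak (%), with dots for single libraries, a horizontal mark for the mean and bars for ± 1 SD (n = 2 per genotype, grey WT, red swc4Δ); crosses show the mean over 1000 shifts of the same peaks. For tRNA genes the swc4Δ libraries lie at 87.6% and 69.5% and the WT libraries at 66.2% and 48.7%, all above the shifted peaks.

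The sixth comparison used 14 gene lists fixed beforehand. The list of mating and haploid identity genes had the most uneven change: of its 8 promoters with a reproducible peak 5 were gained and 0 lost (odds ratio 13.5, adjusted p = 0.00492, Fisher's exact test). The odds ratio was 7.64 without swc4Δ replicate 2, 33.1 with promoters of 300 bp and 63.5 without IV, V, VIII and XI, past the threshold in each. The 5 were BAR1, STE2 (the α-factor receptor), STE6 (the a-factor exporter) and the a-factor genes MFA1 and MFA2, all of which are used by cells of mating type a. STE2 had folds of 4.18 and 2.76 in swc4Δ and no peak in WT. MF(ALPHA)1 and SAG1, used by cells of mating type α, were not in the list and were among the leading losses. STE6 and MFA1 lay on XI and IV, and the other 3 on VI, IX and XIV. The region of MFA2 also held a peak of WT replicate 1, with a fold of 1.99.

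Ribosomal protein genes were the other list past the threshold, with 2 gained (RPL18B and RPL4B) among 126 reproducible promoters (odds ratio 0.123, adjusted exact p = 9.02e-04). The odds ratio was 0.256 without WT replicate 1 and 0.0554 with promoters of 300 bp. This under-representation did not pass without IV, V, VIII and XI (odds ratio 0.220, adjusted exact p = 0.431), which left 1 list past it, whereas 3 lists passed with equal numbers of peaks, with promoters of 300 bp or without swc4Δ replicate 2. Ribosomal protein promoters were open in nearly all cases, at 127 and 118 of 137 in WT and 132 and 121 in swc4Δ, with 113 open in all 4 libraries. A promoter with a WT peak cannot be gained, so few of them could be. The low odds ratio therefore partly follows from how gains were defined and cannot show that these promoters resist gains. Among SWR1 and NuA4 subunits 4 of 10 reproducible promoters were gained, those of SWR1, TRA1, RVB1 and SWC5 (odds ratio 5.37, adjusted exact p = 0.0645), and 3 of these genes lie on IV or VIII. In the subtelomeric helicase and seripauperin families 3 of 5 were gained (PAU10, PAU20 and PAU4; odds ratio 12.1, adjusted exact p = 0.0539) and 1, PAU17, was lost. Members of these families share much of their sequence. Telomere maintenance and silencing had 3 of 8 gained (SIR1, TBF1 and YKU70; adjusted exact p = 0.140), and cell cycle genes 4 of 16 (CLB2, SWI4, CLB3 and MBP1; adjusted exact p = 0.218). Histone and glycolysis genes had 0 gained and 0 lost among 10 and 18 reproducible promoters. Gains numbered 1 of 8 for RNA polymerase III (RET1), 1 of 7 for RNA polymerase I (RRN3), 2 of 7 for ribosome biogenesis (EBP2 and NOG1), 2 of 15 for DNA repair (DNA2 and RAD9), 3 of 26 for stress genes (MSN2, HSC82 and SSB1) and 2 of 21 for the cell wall (PIR3 and SLT2). None of these passed the threshold, and apart from PAU17 no listed promoter was lost. Over all reproducible promoters 314 of 2817 were gained. Many named genes lie on chromosomes rich in gains or set apart. RRN3, EBP2, SIR1 and PIR3 lie on XI, and RPL4B, CLB3, MBP1, RAD9, SSB1 and PAU10 on IV. DNA2 and SLT2 lie on VIII and SWI4 on V. Apart from the SWR1 and NuA4 subunits, the rest lie on the other 12 chromosomes. Peaks of the other genotype lay in the same merged region, outside the promoter, at RPL18B, CLB2, MSN2, PIR3 and PAU17.

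The last comparison set the authors' genotype lists beside the library lists. The swc4Δ list held 2602 regions over 1438 kb and the WT list 1002 regions over 519.8 kb. Of the WT regions 93.3% overlapped the swc4Δ list, while 34.6% of the swc4Δ regions overlapped the WT list. Of the 1701 regions only in the swc4Δ list, 961 (56.5%) overlapped a peak in at least 1 WT library and 612 in both. The ratio of swc4Δ to WT regions was 4.51 on XI, 3.18 on IV and 2.34 on the other 12 chromosomes. These lists have no replicates and an unstated method, so no test was made between them.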

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

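Repeats without IV, V, VIII and XI and without these and XII, all alternatives for chromosome XI, the terminal 1 kb and snoRNA genes, and equal numbers of peaks and left-out libraries for gene lists and promoter counts were chosen after seeing the data. Gained regions were 193 with equal numbers of peaks, 81 without IV, V, VIII and XI, 65 without XII too and 359 to 759 without 1 library. Lost regions were 20 at the stricter threshold, 143 with summits and 114 to 288 without 1 library. Among gains the tRNA odds ratio was 1.03 at the stricter threshold, 1.05 without IV, V, VIII and XI, 0.793 without XII too and 0.378 to 1.21 without 1 library, that of chromosome ends 0.742 with ends of 10 kb and 1.04 to 1.91 without 1 library, that of promoters 0.187 to 0.891 and that of gene bodies only 0.851 without the 4 chromosomes and XII and 0.783 to 6.92 without 1 library, and that of snRNA genes, with 1 gained region, was 0 at the stricter threshold, with 50% overlap and with summits. Among losses the tRNA odds ratio was 0 at the stricter threshold, where it missed the threshold with 20 regions, 0.0766 with equal numbers, 0.0943 with summits, 0.176 with the replicate block and 0 to 0.457 without 1 library, below 1 throughout. That of snoRNA genes, with 2 lost regions, was 0 there, 0.737 with 50% overlap and 0.477 to 2.26 without 1 library. Without IV, V, VIII and XI peaks per library differed by -72.5 (swc4Δ minus WT), the Jaccard index within minus between genotypes was 0.0466 instead of 0.0995 and snoRNA occupancy differed by -2.50 points (without XII too, -99.5, 0.0470 and -2.83); without 1 library the last ran from -3.29 to 9.87 points. The cause of these changes was not tested, beyond the fewer regions left. The odds ratio of chromosome XI among gains and the differences in tRNA, promoter and terminal 1 kb occupancy kept their direction in every alternative run (tRNA 12 to 30.2 points, promoters 0.354 to 13.5), and the mating list passed in each that gave a finite odds ratio. At the stricter threshold its odds ratio was infinite and has no value here.

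Deviations of same-numbered libraries correlated weakly across regions, at 0.0782. The replicate block called gains and losses between same-numbered libraries, so its odds ratios concern another quantity than the main ones. With it the odds ratio of chromosome ends was 1.49 among gains and 0.447 among losses, and both passed the threshold. That of snoRNA genes was 0.337 among gains, which passed, and 0.675 among losses. These calls rest on counts that were not independent. Outside the block, chromosome ends among losses were at 0.217 without WT replicate 1. Of the 18 blocked results 14 kept direction and call. Of the 3 ways to split the libraries into pairs, genotype gave 397 regions found in both libraries of 1 pair only. The split by replicate number gave 172 and the remaining split 59, too few splits for a share under 0.05. Of the 172, 153 were found only in both replicate 1 libraries, which held the longer list of each genotype. Whether list length or another factor shared by same-numbered libraries gave this was not tested. Background pileups of 22.6 to 25.5 fragments limit what was called: weak peaks near the threshold may be missed in 1 library and called in another.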

Other observations

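Tests of explanations were chosen only after the result they bear on was seen, except the test with equal numbers of peaks, and the rules of the tests against promoters and of relative fold were made stricter after their outcomes were known.

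Promoters of ribosomal protein genes were open in 92.7% and 86.1% of cases in WT and 96.4% and 88.3% in swc4Δ, against 17.2% to 24.3% after shifting, whereas all promoters together reached 46.3%, 38.6%, 55.9% and 44.6%. Over all peaks in the outer 20 kb, the median fold percentile within the list was 63.5 and 72.8 in WT and 51.6 and 63.9 in swc4Δ, with swc4Δ replicate 1 not apart from its other peaks (adjusted permutation p = 0.185), and in shared regions it was 72.6, 70.7, 69.4 and 78.1. Among sugar genes, the leading gains at HXT13 (V, 23466 to 23872) and at IMA5 and HXT8 (X, 26308 to 26690) lay just beyond the outer 20 kb of the left chromosome ends, and so were not counted in that class.

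Gains were concentrated on XI, IV and VIII. Greater depth of the swc4Δ libraries would raise peaks everywhere, but the mean number of peaks on the other 12 chromosomes was 0.955 times that of WT, against 2.73 times on XI. Setting apart chromosomes with more swc4Δ peaks lowers the first ratio. Its mean also hides replicate 1 above and replicate 2 below both WT libraries (1814 and 1281 against 1698 and 1542). In neither did these 12 rise as XI did (345 and 288 peaks against 125 and 107). Opening of promoters on XI does not cover the gains in gene bodies only, which were 37 of 113 there and 8 of 81 on the other 12 chromosomes (Fisher's exact p = 2.35e-04), while the promoter shares themselves, 62.8% and 70.4%, left it open for the rest (p = 0.287). A candidate explanation for XI is extra copies of whole chromosomes in the swc4Δ cells, since the lists used 1 background for the genome. Relative fold on XI was at least 1.18 in swc4Δ and at most 0.986 in WT. The mean rise was 0.270, against a largest change of -0.159, on III, among the other 12 chromosomes, with gains in 10 of 10 equal segments. That rise was well short of the doubling that 1 extra copy in every haploid cell would give if fold scaled with copies. Its size was not tested against any copy number, so the explanation stays only a candidate for XI. It is left open for IV, where the rise, from at most 0.993 to at least 1.05 and 0.113 in the mean, was smaller than the fall on III, and for VIII, where swc4Δ replicate 1, at 0.974, was level with the higher WT library, at 0.972; read coverage outside peaks was not analysed here, and loss of SWC4 itself stays untested because it is shared by the same libraries.

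More tRNA genes had a peak in swc4Δ. Equal list lengths did not remove it over all chromosomes: with 2115 peaks in each list the difference was 15.3 points. The shares were 64.4% and 48.7% in WT and 75.3% and 68.4% in swc4Δ. The 2 WT libraries thus lay further apart than the nearest libraries of the 2 genotypes. That test was not run without IV, V, VIII and XI, so it argues against longer lists as the only source over all chromosomes and no further. A shift shared with promoters is left open: on the other 12 chromosomes tRNA genes split 11 gained to 0 lost and promoters away from tRNA genes 81 to 62 (Fisher's exact p = 0.00319; merged regions 8 to 0 and 53 to 48, p = 0.00874), yet tRNA genes were no more common among gained regions there (odds ratio 1.05, exact p = 0.846). Extra copies of whole chromosomes cannot be told apart as a partial source: on the other 12 chromosomes the difference was 14.0 points, with swc4Δ replicate 2 below WT replicate 1. Reads shared between tRNA genes of 1 family were not tested, and an effect of SWC4 loss on tRNA genes stays a hypothesis.

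Of 7 genes used by mating type a 5 had gained promoters, and of 4 used by mating type α, a group chosen after seeing the losses, 2 had lost ones. Of the 7 a-specific genes 6 had a promoter peak in more swc4Δ than WT libraries and 0 in fewer; of the 4 α-specific genes 3 went the other way and 0 with it; and of 11 genes used by both types 1 went each way. Extra copies do not account for this, as 3 of the 5 gained a-specific genes lie on the other 12 chromosomes. Each WT library had a promoter peak at 0 of the 7 a-specific genes and at 4 of the 4 α-specific ones. The swc4Δ libraries had 6 and 5 of the 7, and 2 and 1 of the 4. A different mating type of the 2 strains may account for this split, although the labels name BY4741, a strain of mating type a, for both. It was the WT libraries whose peaks were at odds with that label. The 3 further genes looked at for a difference in mating type, ASG7, MF(ALPHA)2 and STE3, decided little. Only 1, MF(ALPHA)2, split as this needs, and it still had a peak in swc4Δ replicate 1 (fold 2.88). ASG7 had no peak. STE3, on XI, had a peak in all 4 libraries, with folds of 2.97 and 1.92 in WT and 2.33 and 1.77 in swc4Δ. As a member of the mating list it was not independent of the result. An effect of SWC4 loss on these promoters was not tested.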
